A study of Mus musculus with 4 samples.

How the data were processed

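Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on pancreas of 8-week-old Ela1-Myc mice, which carry a c-Myc transgene under control of the elastase 1 promoter, a promoter of acinar cells. Per the labels, the Ptf1a library came from 1 mouse and the c-Myc library from a pool of 3 mice. An input library was made for each: the input for Ptf1a came from 5 mice, of which the Ptf1a mouse was one, and the input for c-Myc from the same 3 mice as its ChIP. Peak lists of the 2 ChIP libraries were analysed. The input libraries were not analysed here.

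Per the labels' protocols, tissue was fixed in 1% formaldehyde for 20 min, sheared to fragments of 300 to 500 bp, and precipitated with 10 μg of the c-Myc antibody. The protocol names the amount for the c-Myc antibody, and that of the Ptf1a antibody is not given in the sources used here. Per the submitters' processing notes, CASAVA 1.8, FastQC 0.9.4, BWA 0.5.9-r16 and MACS 1.4.1 were used with the mouse build mm9. The roles of the tools, their parameters, the peak threshold and the use made of the inputs are not given in the sources used here.

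Each deposited list holds the chromosome, start, end, name and score of every peak. The authors deposited 1 list per library, and the c-Myc library itself pools 3 mice. The score in the deposited lists is the peak caller's value for each peak. No file header or label states its scale, and it does not go below 50.0 in either list. It was used to rank, filter and compare peaks within a list. Medians and shares above a limit are given for each list as descriptions, without a test between lists, and the scores of overlapping partners were correlated across pairs. Neither list gives read counts, so the sequencing depth is unknown and the lists cannot show how complete they are. Coordinates are given on mm9, counted from 1.

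A peak was called shared when at least 1 bp of it overlapped a peak of the other list. The number of shared peaks was set against 1000 random placements of the list on the same chromosomes with peak widths kept, one-sided. Placements were limited to the stretch between the first and the last peak of either list on each chromosome. Each peak was placed singly, so the grouping of peaks was not kept. Gaps of the assembly were to be avoided, but without the mm9 sequence they were not. Gaps hold no peaks, so the chance number is too low by an unknown amount. Multiples of chance below refer to these placements. The smallest p that 1000 placements can give is 0.001. Median scores of shared and unshared peaks were compared within each list by a two-sided permutation test with 100000 resamples, for which the smallest p is 1e-05. Differences of medians carry 95% bootstrap intervals from 2000 resamples. Shares of peaks carry 95% Wilson intervals, which cover counting error only. The share of each list on each of 20 assembled chromosomes was compared between lists by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. The threshold was 0.05 throughout. With 1 library per factor there is no replicate error. All tests describe these 2 lists, peaks are not replicates, and no p-value here measures variation between mice.

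The peaks named in the text are the 10 with the highest scores in each list (ties broken by width, then position) and the 10 shared peaks with the best worse rank in the 2 lists. This rule, the tests and the alternatives were fixed before the data were examined, except where stated. Alternatives were other definitions of a shared peak (50% of the narrower peak covered, or midpoints within 500 bp), only peaks with a score of 100 or more, only the 1000 highest-scoring peaks of each list, only assembled chromosomes without Y and M, all peaks set to 500 bp, and shifts of 10 to 100 kb in place of random placement.

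The share of peaks at promoters, the genes near peaks, 14 fixed gene lists and sequence motifs had also been planned. They were not analysed here: the gene table at hand is on GRCm38.p6, the peaks are on mm9, and coordinates were not converted between builds. Peaks are therefore named by position only.

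Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The overlap test was tested on simulated data: of 5464 randomly placed Myc peaks, 500 and 2000 were set onto Ptf1a peaks, and 500 and 1973 overlaps above chance were recovered. The simulated peaks were placed singly and at random, as in the test itself. The recovery therefore checks the counting and does not show how the test behaves when peaks stand in groups.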

Results

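The occupancy of Ptf1a and c-Myc was profiled in the pancreas of Ela1-Myc mice. Ptf1a is a basic helix-loop-helix transcription factor that drives the acinar programme of the pancreas. c-Myc is a factor of the same structural family that promotes growth and proliferation, and in these mice a transgene adds to its expression in acinar cells. The series title places the work in the maturation of pre-acinar to acinar cells, and the comparison made here is where the 2 factors were found on the genome and how often at the same place. Each factor was represented by 1 library, so no value below has a replicate error.

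The Ptf1a list held 17632 peaks and the Myc list 5464. Ptf1a peaks were narrow, with a median width of 515 bp (quartiles 416 and 623 bp). Myc peaks were wider, with a median of 834 bp (quartiles 701 and 970 bp), a difference of 319 bp (95% bootstrap interval 311 to 326 bp). The Ptf1a peaks covered 9545.9 kb of the genome and the Myc peaks 4781.8 kb. The median score was 116 in the Ptf1a list (quartiles 70.5 and 266) and 75.2 in the Myc list (quartiles 59.5 and 106). A score of 100 or more was reached by 56.6% of Ptf1a peaks and by 28.7% of Myc peaks, while 14.5% and 26.0% of peaks lay below 60, close to the lowest score in the lists. The antibodies and the number of mice differed between the libraries and the depth of both is unknown, so these figures describe the lists and do not rank the factors by binding.

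The Ptf1a peak with the highest score lay on chromosome 9 at 95093855 to 95095358 (score 3195.56) and overlapped a Myc peak. The next, on chromosome 1 at 154050174 to 154050955 (score 3182.12), had no Myc peak. A further 13 Ptf1a peaks were tied at a score of 3100, so the order among the strongest sites is not resolved. Why so many peaks hold this score is not stated, so they may not be weaker than the 2 peaks named first. Of the 13 the widest was on the mitochondrial genome (M, 1 to 6512), and it had no Myc counterpart. The mitochondrial genome is present in many copies per cell, and no input was set against it here. The others among the 10 highest were on chromosome 12 at 93091950 to 93093796, on chromosome 6 at 30588141 to 30589698, on chromosome 8 at 114228415 to 114229635, on chromosome 4 at 117280570 to 117281780, and on chromosome 17 at 73287352 to 73288399, all of which overlapped a Myc peak. The last of them, on chromosome 4 at 109426788 to 109427828 and on chromosome 9 at 94559665 to 94560691, did not. In all, 6 of the 10 Ptf1a peaks were shared, but only 4 when Myc peaks needed a score of 100 or more and 3 when only the 1000 highest Myc peaks were admitted. The tied peaks among these 10 are the widest of the 13. Wider Ptf1a peaks were more often shared, 6.66% in the narrowest of 5 equal parts by width and 25.3% in the widest, so the tie rule may raise this count.

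The strongest Myc peak lay on chromosome 17 at 39979551 to 39986248. At 6698 bp it was also the widest Myc peak, and its score of 2073.91 stood well above the next in the list (669.9). It overlapped a Ptf1a peak. Whether this sequence is present in many copies, which would pile up reads in any library, was not tested. Of the other 9 among the 10 highest-scoring Myc peaks, only the site on chromosome 14 at 115441108 to 115442546 (score 574.91) overlapped a Ptf1a peak. The sites without one included chromosome 4 at 44078081 to 44079612 (score 669.9), chromosome 3 at 88099959 to 88101755 (score 603.43), chromosome 2 at 158186472 to 158188005 (score 596.38) and chromosome 16 at 4557568 to 4559635 (score 545.48). The remaining sites were on chromosome 10 at 76495487 to 76497127, chromosome 3 at 137805938 to 137807507, chromosome 7 at 17368474 to 17370459 and chromosome 4 at 133465920 to 133467399, with scores from 536.68 down to 508.54. In all, 2 of the 10 Myc peaks were shared, and 1 under either of those limits on the Ptf1a peaks.

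To ask whether the factors were found at the same sites, the lists were overlapped. Myc peaks were often found where Ptf1a peaks were. Of the Myc peaks, 2261 of 5464 overlapped a Ptf1a peak, a share of 41.4% (95% Wilson interval 40.1 to 42.7%). Of the Ptf1a peaks, 2356 of 17632 overlapped a Myc peak, a share of 13.4% (12.9 to 13.9%). Thus 3203 Myc peaks and 15276 Ptf1a peaks were found in 1 list only. Random placement gave 57.5 ± 7.58 overlapping Myc peaks (SD over 1000 placements, highest 88), so the observed number was 39.3 times that of chance (one-sided permutation test by random placement, p = 0.001, the smallest it can give). For Ptf1a peaks placement gave 59.9 ± 7.62 (highest 83), and the observed number was 39.3 times that of chance (permutation p = 0.001). When each Myc peak was instead moved by 10 to 100 kb, 166 ± 11.8 overlapped a Ptf1a peak (highest 205), and the observed number was 13.6 times that mean (permutation p = 0.001). The shares depend on how many partners are admitted: among peaks with a score of 100 or more in both lists, 34.2% of Myc peaks and 5.61% of Ptf1a peaks were shared, and among the 1000 highest of each list 8.90%.

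**Figure D1:**
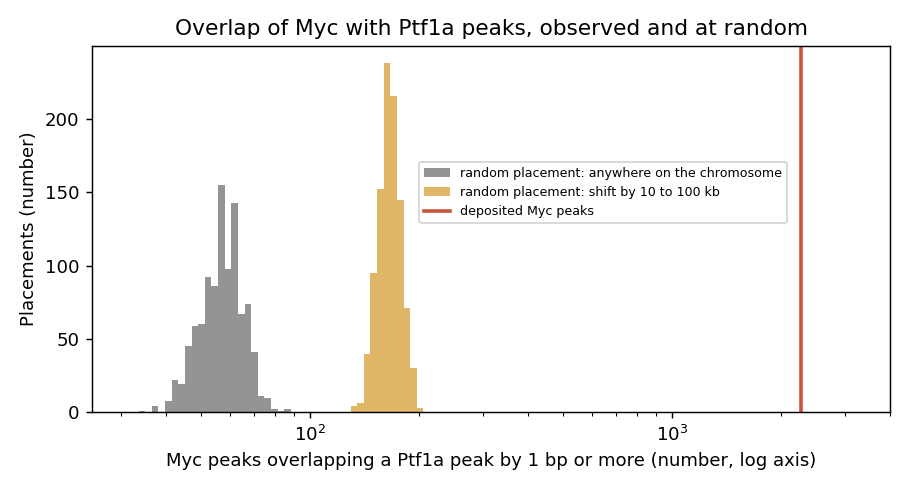
Number of Myc peaks that overlap a Ptf1a peak by at least 1 bp (x axis, log scale) in the deposited lists (vertical line) and in 1000 random placements of each of 2 kinds (histograms; y axis, number of placements). The deposited lists gave 2261 overlaps, while placement anywhere on the chromosome gave at most 88 and shifts of 10 to 100 kb at most 205.

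The overlapping peaks lay close to each other's centres. There were 2368 overlapping pairs, with a median distance between midpoints of 110 bp (quartiles 48 and 221 bp). In 46.2% of pairs the midpoints were at most 100 bp apart and in 77.8% at most 250 bp. In 55.3% of pairs the narrower peak lay wholly within the wider one. Most overlaps were between 1 peak of each list: 105 Myc peaks held 2 or more Ptf1a peaks, and 12 Ptf1a peaks touched 2 or more Myc peaks.

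The shared sites highest in both lists were led by the wide site on chromosome 17, whose copy number was not tested and where the Ptf1a peak at 39979718 to 39985849 (score 2425.1, rank 33) lay wholly inside the strongest Myc peak. On chromosome 19 a Myc peak at 58801930 to 58803861 (score 338.41) overlapped a Ptf1a peak at 58801714 to 58803819 (score 2233.86). Chromosome 5 held 3 of the 10: Myc peaks at 144943354 to 144945961 (score 445.41), 54067515 to 54068630 (score 309.02) and 139339445 to 139340517 (score 245.15), whose Ptf1a partners scored 2039.95, 1820.03 and 2583.69. Chromosome 4 held 2, at 122937000 to 122938407 and 136992850 to 136993867 in the Myc list. The others were the Myc peaks on chromosome 12 at 93092077 to 93093164, on chromosome 2 at 26080722 to 26081542 and on chromosome 7 at 138399840 to 138401556. The partners of the first 2 of these scored 3100 in the Ptf1a list.

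Several shared sites lay near one another on chromosome 11. Chains of Ptf1a peaks were formed by joining peaks at most 12.5 kb apart, and the chain with the most peaks lay at 57765679 to 57824601, a stretch of 58.9 kb. It was chosen after the chains were seen. It held 18 Ptf1a peaks, with scores from 58.6 to 2361.78, and 11 of these overlapped a Myc peak. The same stretch held 11 Myc peaks, with scores from 51.4 to 261.86, and 10 of these overlapped a Ptf1a peak.

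**Figure D2:**
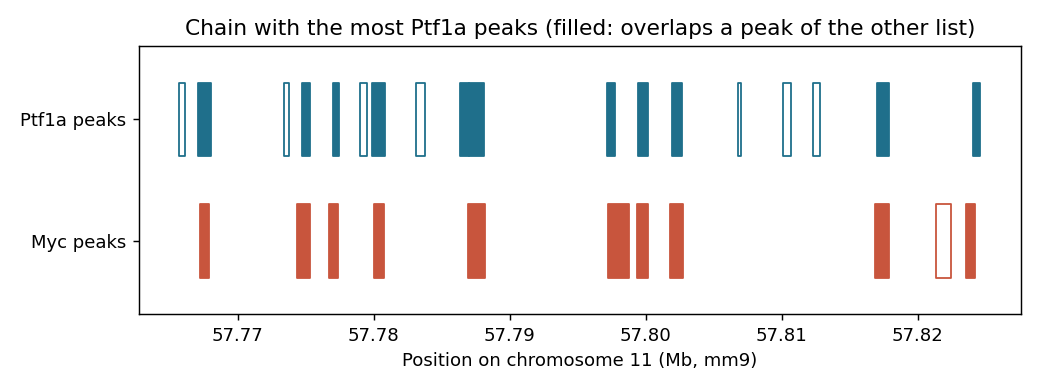
Peaks of Ptf1a (upper row) and Myc (lower row) on chromosome 11 (x axis, position in Mb on mm9) in the chain with the most Ptf1a peaks; boxes are drawn to scale, and filled boxes overlap a peak of the other list. Of the 18 Ptf1a peaks 11 are filled, and of the 11 Myc peaks 10.

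Shared Ptf1a peaks had higher scores than unshared ones. Their median score was 177 against 111, a difference of 65.6 (95% bootstrap interval 56.3 to 77.3; permutation test, p = 1e-05, the smallest it can give). The difference was 22.2 without the 5% widest and 5% highest-scoring peaks of each list, a limit that narrows the range of the score itself. It was 143 among peaks with a score of 100 or more and 176 among the 1000 highest of each list, which also select peaks by score. Among peaks of similar width it was seen only in the widest of 5 equal parts of the list (136, interval 85.5 to 186); in the 4 others it was -0.14, -5.41, -1.0 and 11.7, with intervals that include 0. The share of Ptf1a peaks with a Myc peak was 8.67% (7.45 to 10.1%) in the lowest of 10 equal parts of the list by score, 16.7% (15.01 to 18.5%) in the last but one and 28.5% (26.4 to 30.6%) in the highest. In the Myc list the median score was 79.9 for shared and 71.5 for unshared peaks, a difference of 8.34 (5.53 to 10.3; permutation test, p = 1e-05). In 5 equal parts of the Myc list by width the difference was between 0.10 and 3.50, and 3 of the 5 intervals include 0. The share of Myc peaks with a Ptf1a peak was 30.4% (26.6 to 34.3%) in the lowest part and 50.6% (46.5 to 54.8%) in the highest. Among peaks with a score of 100 or more in both lists the Myc difference was 5.39 (bootstrap interval 0.21 to 12.9) and no longer passed the permutation test (p = 0.0686). Across the 2368 pairs the scores of the partners were only weakly related (Spearman's rho 0.052, permutation p = 0.0114; Pearson's r of log10 scores 0.0625, permutation p = 0.00233). This correlation is across sites, which are not independent replicates.

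**Figure D3:**
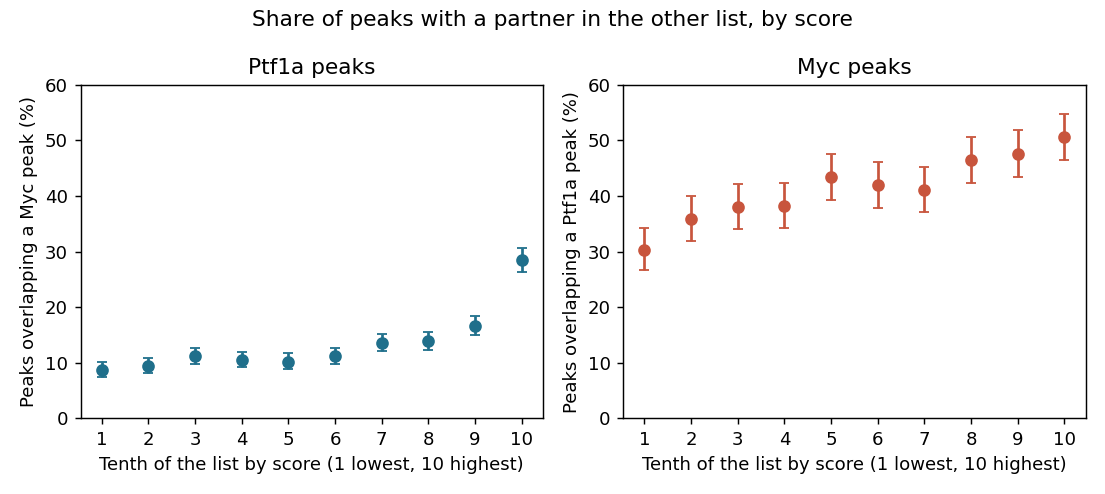
Share of peaks (y axis, percent, with 95% Wilson intervals) that overlap a peak of the other list, for 10 equal parts of each list by score (x axis, 1 lowest to 10 highest). The share among Ptf1a peaks (left) goes from 8.67% in the lowest to 28.5% in the highest part, and among Myc peaks (right) from 30.4% to 50.6%.

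Both lists had peaks on all autosomes and on X, and neither had any on Y. Chromosome 11 had the most peaks per Mb in both lists, with 11.3 Ptf1a and 4.05 Myc peaks, followed by chromosome 19 with 11.3 and 3.35. The other end among the autosomes was chromosome 14, with 5.67 Ptf1a and 1.502 Myc peaks per Mb. Chromosome X had 199 Ptf1a peaks and 45 Myc peaks, or 1.24 and 0.281 per Mb. Per Mb the autosomes together held 5.86 times as many Ptf1a peaks and 8.06 times as many Myc peaks as X. Densities refer to the stretch between the first and last peak on each chromosome. No chromosome differed between the lists in its share of peaks after adjustment (Fisher's exact tests over 20 chromosomes, 0 past the threshold, 3 at an unadjusted p under 0.05). The nearest were chromosome 7, with 7.49% of Myc and 6.39% of Ptf1a peaks, and chromosome 11, with 8.79% and 7.61% (Fisher's exact test, adjusted p = 0.0531 for both).

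**Figure D4:**
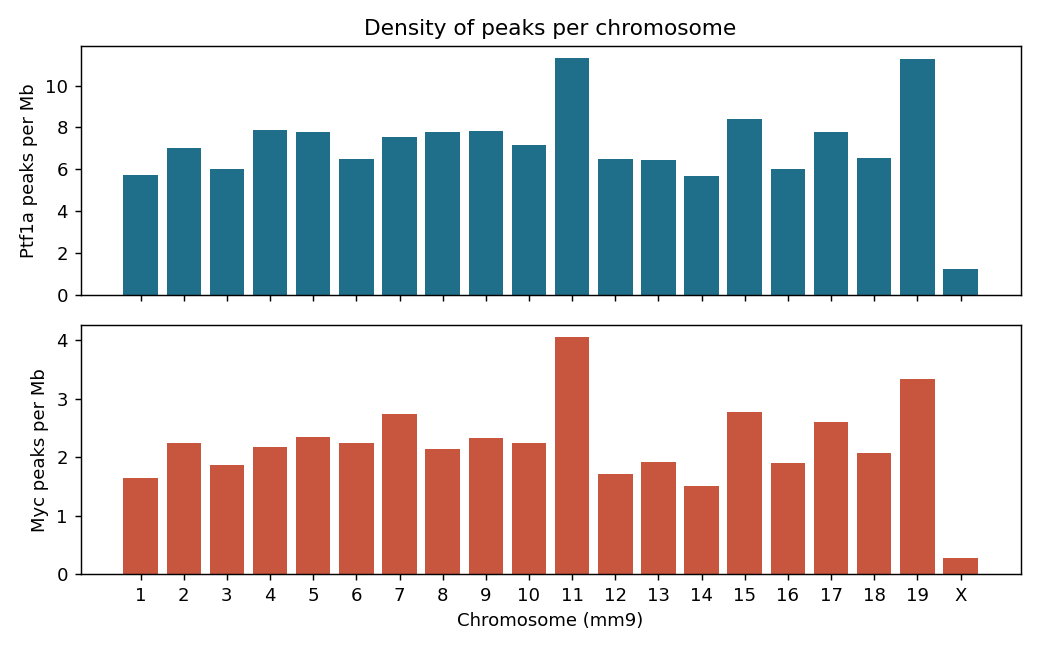
Peaks per Mb (y axes) of Ptf1a (top) and Myc (bottom) on each mm9 chromosome (x axis); each bar is 1 list, with no replicate. Chromosome 11 is the densest in both lists, and X the sparsest, with 1.24 Ptf1a and 0.281 Myc peaks per Mb.

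Myc peaks on X had fewer Ptf1a peaks to overlap, and a smaller share of them was shared. Of the 45 Myc peaks on X, 6 overlapped a Ptf1a peak (13.3%, 6.26 to 26.2%), against 2254 of 5417 on the autosomes (41.6%; Fisher's exact test, two-sided, p = 5.66e-05, chosen after the counts were seen). On single autosomes the share ranged from 36.9 to 47.7%. Random placement gave 0.067 shared Myc peaks on X (highest 2) and 56.5 on the autosomes (highest 84), so both numbers were above chance (permutation p = 0.001 each). Relative to chance the number was 89.6 times the mean of placements on X, from 6 shared peaks, and 39.9 times that mean on the autosomes, so the order on this scale is the opposite of that of the shares. The difference between these ratios was not tested.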

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

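Of 32 values obtained under the alternatives for the overlap, score and chromosome comparisons, 31 kept their direction and their side of the threshold. These values are not separate tests. With every peak 500 bp wide, overlap is nearly the same rule as midpoints within 500 bp, and both gave 2169 shared Myc peaks. Shifts leave the shares as they are and change only the chance level. Leaving out Y, M and unplaced sequence kept 5462 of 5464 Myc peaks. The exception among the 32 was the score of shared against unshared Myc peaks. Its difference of 5.39 among peaks with a score of 100 or more did not pass (permutation p = 0.0686, with 1570 Myc peaks left), although its bootstrap interval of 0.21 to 12.9 leaves out 0. The cause was not tested. Under the other alternatives the difference ranged from 5.27 to 13.2. The 13.2, from the 1000 highest peaks of each list, passed the permutation test (p = 0.0337), but its bootstrap interval of -2.09 to 28.3 includes 0. The share of Myc peaks with a Ptf1a peak ranged from 8.90 to 41.4% and that of Ptf1a peaks with a Myc peak from 5.61 to 13.4%. The lowest values came from alternatives that keep fewer peaks to overlap. Other definitions of overlap kept the Myc share between 39.6 and 39.7%. Without the 5% widest and 5% highest-scoring peaks, an alternative chosen after seeing the data, the shares were 32.5 and 10.4%. The difference in score of Ptf1a peaks ranged from 22.2 to 176, with both ends from alternatives that select peaks by their score. Of the 10 highest-scoring peaks, 1 to 2 Myc and 3 to 6 Ptf1a peaks were shared under the alternatives that kept all 10. The count of chromosomes past the threshold was 0 under both score limits (Fisher's exact tests; 3 at an unadjusted p under 0.05 in the full lists). Placement that keeps the distance to genes, and all alternatives for promoters, genes and motifs, were not run, for want of mm9 gene positions. With 1 library per factor no replicate could be left out, and with the depth unknown a site in 1 list only may have been missed in the other: 26.0% of Myc peaks scored below 60. No paired analysis was possible because each factor has 1 library.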

Other observations

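The tests of crowding and of neighbours, the further split of the widest peaks, and the reading of the result with 500 bp peaks as a test of contact were chosen after seeing the data. Peaks of both factors stood in groups more often than randomly placed peaks, although 7737 Ptf1a and 3788 Myc peaks stood alone. Chains of 3 or more Ptf1a peaks, each at most 12.5 kb from the next, numbered 1455 and held 33.7% of all Ptf1a peaks, against 2.51% in 100 random placements (highest 3.04%). Of Myc peaks 10.9% lay in 177 such chains, against 0.271% at random (highest 0.622%). Ptf1a peaks in chains overlapped a Myc peak more often than Ptf1a peaks standing alone, 17.6% (16.7 to 18.6%) against 10.5% (9.87 to 11.2%; Fisher's exact test, p = 8.92e-33). The same held for Myc peaks in chains of their own, 49.5% (45.5 to 53.5%) against 39.9% (38.3 to 41.4%; Fisher's exact test, p = 1.11e-05). Peaks in chains also had higher median scores, 134 against 105 for Ptf1a and 77.1 against 74.9 for Myc, and sharing was higher in the highest than in the lowest of 10 equal parts of each list by score, though not among the 25 highest-scoring Myc peaks, of which 5 were shared. Peaks of a chain are not independent, so these p-values are too small. Myc peaks that overlapped no Ptf1a peak were near one more often than placed peaks: with a median distance of 18.2 kb, 37.5% (35.9 to 39.2%) had a Ptf1a peak within 10 kb, against 10.2% of placed peaks that overlapped none (highest of 1000 placements 12.0%).

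In the chain with the most Ptf1a peaks, on chromosome 11 at 57765679 to 57824601 (mm9), 8 of the Myc peaks made up the largest Myc chain (57767224 to 57802700). In the next largest Ptf1a chains, 2 of 16 peaks on chromosome 5 at 124416752 to 124495779, 2 of 16 on chromosome 11 at 74301147 to 74368548, 6 of 15 on chromosome 8 at 114209673 to 114269917 and 5 of 14 on chromosome 11 at 94021741 to 94072325 overlapped a Myc peak. On chromosome 4 at 115511316 to 115523798, all 5 Myc peaks of a chain overlapped a Ptf1a peak, while on chromosome 5 at 113564881 to 113584653 only 1 of 6 did.

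The overlap of the lists far above chance has several possible technical explanations. Crowding of both factors into the same regions at a scale of 10 to 100 kb is argued against as the whole of it. Shifts of 10 to 100 kb left 165.7 overlapping Myc peaks on average, against 2261 observed. Crowding within less than 10 kb was not tested by these shifts. Contact through width alone is argued against by the midpoints. Over the pairs, the median ratio of their distance to the distance at which the peaks would just touch was 0.151 (95% bootstrap interval 0.143 to 0.158). Midpoints lying anywhere within touching distance would give about 0.5. A few extreme regions are argued against, since 32.5% of Myc peaks were still shared without the widest and strongest peaks. It stays open that open chromatin was pulled down by any antibody, as no list from another antibody was used. The weak relation of the scores (rho 0.0521) does not decide it. Background present in both libraries at many sites is not excluded either, since the inputs were not analysed and the use made of them is unknown. Binding of both factors at these sites remains among the hypotheses.

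The higher score of shared Ptf1a peaks could come from width, since wide peaks score higher (Spearman's rho 0.657 across peaks) and touch others more readily. In the 4 narrower of 5 equal parts by width the difference was -0.14, -5.41, -1.0 and 11.7, and all 4 intervals include 0. Much of the spread of log10 scores was left within parts (SD 0.300 against 0.392 in the whole list). Since width and score rise together, a split by width is also partly a split by score, and it cannot tell width from the strength of a site. In the widest part the difference was 136, and it was above 0 beyond its interval in 4 of 5 further parts by width, which leaves width open there as part of the cause. With every peak set to 500 bp, so that width could not affect contact, the difference was 68.93 (59.4 to 82.2), which argues against contact by itself. Stronger or more open sites being shared more often stays open.

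The low density of peaks on X may have a technical cause. A single copy of X in male mice would lower the signal there, but the sex of the mice is not among the labels used here. The densities on X, 1.241 Ptf1a and 0.2806 Myc peaks per Mb, were set against those of autosomal peaks with a score of 200 or more, 2.34 and 0.114. With a score of 100 or more the autosomal densities were 4.123 and 0.6494, above X in both lists. Either limit assumes how the score falls when the signal is halved. Since neither the scale nor the depth is known, a density on X below a limit does not exclude this cause. X peaks were not clearly weaker than autosomal ones, with a difference of median scores, X minus autosomes, of -14.12 for Ptf1a (bootstrap interval -24.4 to 6.66) and -0.93 for Myc (-11.9 to 14.5), so loss of X peaks under the threshold is undecided too. The density of genes on X was not tested.

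Of the 25 highest-scoring Myc peaks 5 overlapped a Ptf1a peak, and of the next 25 peaks 17 did. The limit of 25 was not among the planned tests, and several such limits were looked at. Of the 50 highest-scoring Myc peaks 44.0% were shared, and of the 100 to 1000 highest between 47.0 and 50.8%. The widest Myc peak and the widest Ptf1a peak outside the mitochondrial genome were at the same place, on chromosome 17 at 39979551 to 39986248 and 39979718 to 39985849. The mitochondrial peak of 6512 bp (score 3100) was in the Ptf1a list alone. Whether these sites are multi-copy sequence that piles up reads was not tested.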
